A study of Mus musculus with 14 samples.

How the data were processed

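RNA-seq compared granule neuron progenitors of 4 control and 4 CHD8 CKO samples, and ChIP-seq was made from wild-type progenitors with 2 CHD8, 2 input and 2 normal IgG samples. Per the labels' protocols, the cells were isolated from the cerebellum at postnatal day 7 on a Percoll gradient, RNA was extracted with Trizol, RNA libraries were directional and started from 1 µg of RNA, and ChIP libraries were made with a ThruPLEX kit. Groups were taken from the labels. All CKO samples were labelled with the Olig1-Cre driver and the controls with Atoh1-Cre (2) or Olig1-Cre (2), so the driver differs with genotype in part. The labels do not say which samples came from separate animals.

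Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.0, DESeq2 1.26.0, Bowtie2 2.2.3, SAMtools 1.9, MACS2 and ChIPseeker 1.22.1, with build mm10; their settings, the annotation and the strand setting are not given in the sources used here. The authors' deposited expression table holds, for 18488 genes, the mean normalised count as a signal over the samples, a log2 fold change with its standard error, the Wald statistic as a score, a p-value and an adjusted p-value, all from DESeq2 as the authors ran it. It holds no value per sample and names neither its samples nor the order of the groups. Recomputation showed that the authors' statistic is the log2 fold change divided by its standard error, and that the adjusted p-value is a Benjamini-Hochberg adjustment over the 15618 genes that have one. The other 2870 genes have no adjusted p (5 of them also no p-value) and had no part in the main tests. They entered the alternative that adjusts over every gene with a p-value, and the closing part counts and names some of them. The lowest mean in the deposited table is 1.01 and the lowest with an adjusted p is 9.40. The authors' log2 fold changes are shrunk to 0: standard errors never exceed 0.198, and their median is 0.193 for means from 10 to 100, 0.0965 for means of at least 1000 and again only 0.102 for means under 2. A small standard error at a low mean is therefore no sign of precision, and fold changes of variable genes are understated.

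Per the file headers, peaks were called with MACS2 2.1.1.20160309 from paired-end fragments at a p-value threshold of 1e-05, with both CHD8 libraries pooled against both inputs pooled, at most 1 fragment kept per position and a mean fragment size of 276 bp. The normal IgG libraries are not in that command. Per the file headers, 34% of CHD8 and 14% of input fragments were removed as redundant, which left 44347463 and 48436005. For each peak the deposited list gives 1-based positions in mm10, a pileup (a coverage signal), a -log10 p and a -log10 q, and a fold enrichment, the ratio of CHD8 to local input. Per the file headers q would not be calculated, yet the deposited list holds positive values for it, so what counts at a q threshold mean is uncertain. Per the file headers the cells behind the peaks carry another abbreviation than in the labels; the labels' description was used.

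Gene names, positions and lengths came from a RefSeq gene table of GRCm38.p6, the same build as mm10. It named 17774 of the 18488 gene identifiers, and 8 of the 513 changed genes are among the 714 without a name. The table used here has no strand and no exons, so summits were set against both annotated ends of a gene in place of its transcription start, and 122 tested genes had a summit at both ends. Random positions (10 per peak, fixed seed) were drawn on the same chromosomes between the outermost annotated gene ends.

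No model could be fitted across the samples, so the authors' adjusted p was used as the test of each gene, with a threshold of 0.05. Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule took Chd8, the 12 largest positive and 12 largest negative log2 fold changes among changed, named genes with a mean of at least 100, up to 4 members per list with the smallest adjusted p, the 8 peaks of highest fold enrichment, and the 6 positive and 6 negative genes with the smallest adjusted p that had a summit within 1 kb. Where a list's members also passed in counts adjusted over the list alone, the p-values of its tested members were adjusted by themselves. Set tests used cameraPR of limma 3.58.1 in R 4.3.3 on the authors' Wald statistic, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 28 lists with at least 2 tested genes; they are two-sided. A correlation estimated from samples could not be used, so which calls would hold with one is not known. Peak shares have Wilson 95% intervals, binding and change were compared with two-sided Fisher exact tests (95% Woolf intervals) and with a Cochran-Mantel-Haenszel test over 10 bins of mean expression, and permutation tests drew 100000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

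The set test, the stratified binding test, the exact test of lists within bins of mean expression, the permutation test of standard errors and the rank correlation were tested on simulated data. With 1 list of 33 genes shifted by 1 SD of the statistic among 15618 genes, the set test found it in 99% of 100 runs, and with no shift it called any list in 1% of runs. These simulated statistics were independent between genes. The 1% therefore does not apply to lists whose members move together. With a planted odds ratio of 0.4 among 15247 genes and call rates that rise with expression, the stratified test recovered a median of 0.402 in 100 runs and called all of them. With no planted effect the plain odds ratio was 1.56, the stratified one 1.03, and 3% of runs were called. For the permutation test of standard errors, a shift of 0.5 SD in 97 genes was called in 95% of 100 runs and no shift in 5%. For the rank correlation these were 100% with a planted slope of 0.05 and 4% with none. With 54 genes drawn from the higher bins and no effect, the exact test within bins called 1% of 100 runs and the plain Fisher test 77%; with 25% more members bound the former called 98%.

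Alternatives were other thresholds of adjusted p and fold change, adjustment over every gene with a p-value, higher minimum means, set tests on ranks, on log2 fold changes and with another preset correlation, stricter peaks, wider windows, stratification, and length given mean expression. Alternatives that need values per sample or exons were not run. The criteria of several tests in the closing part were revised after a first result had been seen, without a change to any deposited value. For cell composition, a distance between medians was added to both tests. For summits at muscle genes, all other genes were the first reference and the fewer summits passed; against genes of like mean expression the difference did not pass, and the label now rests on a bound of 50% on the share itself, chosen with the share known. For muscle genes without an adjusted p, a binomial test was dropped because the list was written after the pattern was seen and its genes can move together. For imprinted genes, the first test held the 3 genes that had prompted it and passed; they were then left out. For standard errors, a comparison with cell cycle and Shh pathway genes was added. Some genes that the naming rule selects are not reported here.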

Results

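The data came from granule neuron progenitors of the cerebellum, the dividing precursors of granule neurons, which were purified on a Percoll density gradient from C57BL/6J mice at postnatal day 7. CHD8 is a chromatin remodelling protein of the CHD helicase family, and the series asked what its loss does in these cells and where it sits on chromatin. RNA-seq was labelled for 4 control and 4 CHD8 CKO (conditional knockout) samples. ChIP-seq of wild-type progenitors comprised 2 CHD8, 2 input and 2 normal IgG samples. Among the controls, 2 were labelled with an Atoh1-Cre and 2 with an Olig1-Cre driver, whereas all 4 CKO samples were labelled Olig1-Cre. The allele was labelled Chd8LF/F in the CKO samples and CHD8+/+ in the controls. That CHD8 was lost in the sequenced progenitors rests on these labels alone. Expression was given as a comparison table by the authors with 1 row per gene, so no value per library, no SD and no depth per RNA-seq library can be stated here, and the standard error of each fold change stands for its spread. The authors' deposited table does not name which group is the numerator of the fold change. Changes are therefore written as positive or negative log2 fold changes, and which of the groups was higher is left open throughout.

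Chd8 itself, the targeted gene, had almost no difference in total transcript level. In the authors' deposited table Chd8 (gene 67772, chromosome 14, positions 52198151 to 52258042, mm10) had a mean normalised count of 4744 and a log2 fold change of -0.06 (SE 0.0955), with an adjusted p of 0.891. A count over the whole gene also takes in exons that Cre does not remove, so this value neither checks the labels nor settles the direction of the table.

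Expression changed in 513 of the 15618 genes with an adjusted p, at an adjusted p below 0.05 (3.28%). Negative fold changes were the more frequent, with 317 genes against 196 positive ones (61.8% negative, 95% Wilson interval 57.5 to 65.9%; exact two-sided binomial p = 1.03e-07 across genes, which are not independent replicates). Changes were mostly moderate, with a median absolute log2 fold change of 0.54. The balance was near even among changed genes with an absolute value of at least 0.5 (136 positive, 152 negative). Among the 24 with at least 1 the balance was the other way, with 18 positive and 6 negative. Genes of skeletal muscle contributed many of the large positive values, and without the genes of the muscle and other cell type lists, a choice made after the data were seen, 160 positive and 317 negative genes were counted.

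The largest positive values among genes with a mean of at least 100 belonged to genes of the contractile apparatus. In the authors' deposited table Myh3 (gene 17883, chromosome 11, 67078273 to 67102291), an embryonic myosin heavy chain, had a log2 fold change of 2.64 (SE 0.172, adjusted p = 7.71e-49), a 6.23-fold difference at a mean normalised count of 367. Actc1, cardiac alpha actin, stood at 2.50 (SE 0.177, adjusted p = 3.87e-41) in the authors' deposited table. H19, an imprinted non-coding RNA, followed with 1.12 (SE 0.189), then Tpm2, a tropomyosin, with 1.05 (SE 0.130) and the imprinted gene Grb10, an adaptor of growth factor receptors, with 0.96 (SE 0.143) in the authors' deposited table. Further positive genes in the authors' deposited table were Pvalb, the calcium buffer parvalbumin, at 0.86, the calcium pump Atp2a3 at 0.82, Inpp5j at 0.82, Myoc at 0.81, Cdh15 at 0.77, Rgs8 at 0.77 and Tspan11 at 0.76, with standard errors between 0.161 and 0.198.

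The largest negative value belonged to Ifi203, an interferon-inducible gene. Among named genes with a mean of at least 100, the next belonged to Fat2, an atypical cadherin of granule cells. In the authors' deposited table Ifi203 had a log2 fold change of -1.35 (SE 0.182, adjusted p = 9.52e-11) and Fat2 (gene 245827, chromosome 11, 55250609 to 55337505) of -1.19 (SE 0.123, adjusted p = 1.64e-18), the latter a 2.28-fold difference at a mean normalised count of 4034. Shisa8 and Il16 both stood at -1.04 in the authors' deposited table, and Cadps2, which acts in dense-core vesicle release, at -0.94 (SE 0.161). The authors' deposited table gave -0.92 for Amer3, -0.90 for the non-coding RNA Mirt1, -0.89 for the potassium channel gene Kcnd2 (SE 0.0979), -0.87 for Runx1t1, -0.84 for Cdh7, -0.82 for the adrenergic receptor gene Adra2c and -0.81 for Ltbp2.

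**Figure D1:**
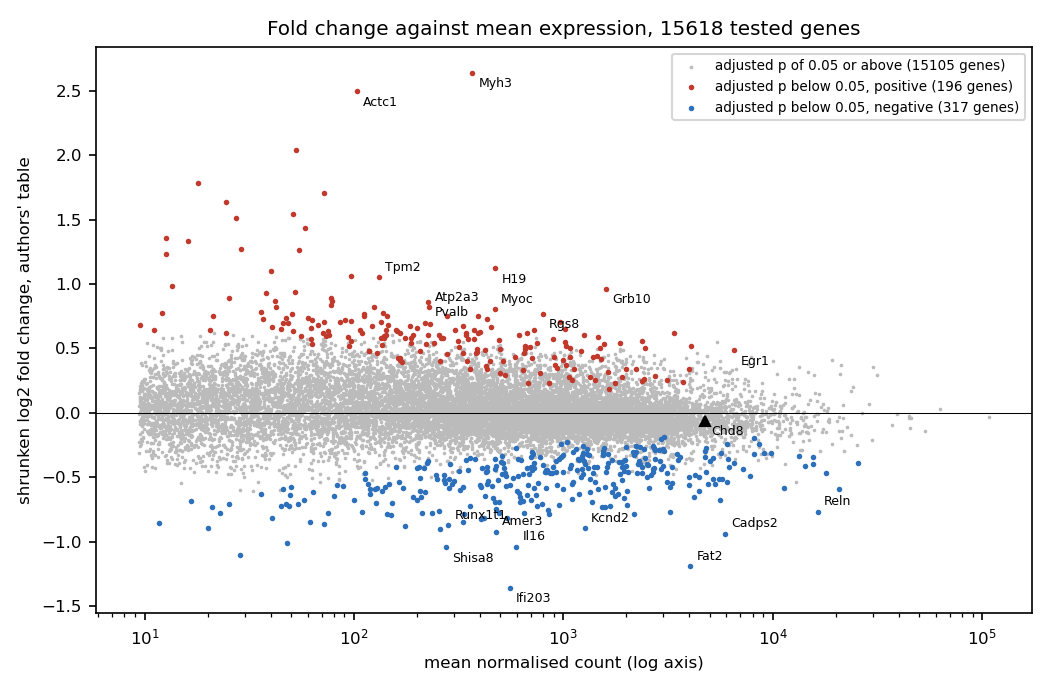
Shrunken log2 fold change of the authors' deposited table (vertical axis) against the mean normalised count (horizontal log axis) for the 15618 tested genes, 1 point per gene, with the 196 positive and 317 negative genes past an adjusted p of 0.05 in colour and Chd8 as a black triangle. Myh3 and Actc1 stand apart at the top with 2.64 and 2.50, Ifi203 lies lowest at -1.35, and Chd8 lies near 0.

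Granule neuron differentiation genes had mostly negative fold changes. Of 33 tested members 9 changed, all negatively, and 13 negative and 3 positive members passed when adjusted over the list alone; the list's median log2 fold change was -0.26 and its set test against all other genes gave an adjusted p of 4.52e-09. Of the 33 members 13 are also in another list. In the authors' deposited table Neurod2, a neurogenic transcription factor, had a log2 fold change of -0.57 (SE 0.0920, adjusted p = 1.92e-07), Reln, the secreted protein reelin made by granule cells, of -0.77 (SE 0.132), Cbln1, a synaptic organiser at parallel fibre synapses, of -0.65 (SE 0.120) and Gabrd, a GABA receptor subunit, of -0.86 (SE 0.166). In the list of granule neuron progenitor identity 2 of 17 members changed, both negatively, and the set test did not pass (adjusted p = 0.363). These were the zinc finger genes Zic1 and Zic4, with -0.39 (SE 0.121) and -0.37 (SE 0.109) in the authors' deposited table. Pax6 (-0.35, adjusted p = 0.331) and Zic2 (-0.28, adjusted p = 0.334) of the same list did not pass in the authors' deposited table. None of the 14 Shh pathway genes, which carry the mitogenic signal of these progenitors, passed the authors' DESeq2 test; 2 had an unadjusted p under 0.05, the median was 0.12 and the set test gave an adjusted p of 0.0632. On ranks and among genes with a mean of at least 100 the same set test passed, with adjusted p of 0.0313 and 0.0331. Ptch1, the Shh receptor and itself a target, had 0.20 (SE 0.0743, adjusted p = 0.125) in the authors' deposited table.

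Neuronal excitability and synapse genes were the lists with the most negative calls by number. As a share of members these calls were at a like level to the 9 of 33 in the granule neuron differentiation list. Among 66 ion channel and neurotransmitter receptor genes 17 were negative, 2 positive and 47 did not pass (24 and 11 adjusted over the list alone; median -0.13; set test adjusted p = 6.48e-06). Beside Kcnd2, the authors' deposited table gave -0.71 for the kainate receptor gene Grik2 (SE 0.125), -0.78 for Kcnj3 (SE 0.142) and -0.74 for Kcnk9 (SE 0.141). In the list of synapse structure and vesicle release 13 of 48 members were negative, 1 was positive and 34 did not pass (20 and 3 adjusted over the list alone; median -0.18; set test adjusted p = 3.20e-09). Slc17a7, a vesicular glutamate transporter, stood at -0.70 (SE 0.140), Unc13a, a vesicle priming factor, at -0.56 (SE 0.117), Lrrtm2 at -0.46 and Epb41l1 at -0.54 in the authors' deposited table. The list of autism-associated genes had 4 negative and 0 positive calls among 54 members (6 and 0 adjusted over the list alone; median -0.08; set test adjusted p = 0.000631), with 3 positive and 11 negative members at an unadjusted p under 0.05 in the authors' DESeq2 test. Its called members included Reln, already given, and Ank2 with -0.29 (SE 0.0917) in the authors' deposited table, and 16 of the 54 members are also in another list. Axon guidance and adhesion genes went both ways, with 7 negative and 1 positive among 63 (8 and 7 adjusted over the list alone) and a set test adjusted p of 0.834. The netrin receptor gene Unc5b stood at -0.66 (SE 0.112), Cdh10 at -0.43, L1cam at -0.55 and Slit1, which codes for a repellent ligand, at 0.75 (SE 0.169) in the authors' deposited table. Of 18 genes of the CHD family and CHD8 partners only Chd3 changed, with -0.37 (SE 0.0919, adjusted p = 0.00400) in the authors' deposited table, while the set test gave an adjusted p of 0.0846 and the authors' deposited table gave Chd7 -0.34 (adjusted p = 0.201).

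Markers of inhibitory neurons and of neural glia lay on the positive side. Of 15 genes of cerebellar inhibitory interneurons 6 changed, all positively (12 adjusted over the list alone; median 0.44; set test adjusted p = 4.85e-10), and of 15 Purkinje cell genes 5 did (8 adjusted over the list alone; median 0.40; adjusted p = 3.20e-09). Of these members 5 and 4 are also in another list, and the called genes Gad1 and Slc32a1 are in both. The results of the interneuron and Purkinje lists are therefore not independent. Gad1 and Gad2, the GABA-synthesising enzymes, both stood at 0.62 (SE 0.152 and 0.164) in the authors' deposited table, beside Kit at 0.52, Slc32a1 at 0.60, Ebf2 at 0.64 and Ppp1r17 at 0.72. All 20 tested Bergmann glia and astrocyte genes and all 18 oligodendrocyte lineage genes had fold changes above 0, with medians of 0.30 and 0.35 and set test adjusted p of 1.20e-05 and 1.01e-05. No single member of these lists passed the authors' DESeq2 test, with 7 and 6 members at an unadjusted p under 0.05. Gdf10 stood at 0.55 (SE 0.187, adjusted p = 0.0804) in the authors' deposited table. All 9 choroid plexus and ependyma genes were above 0 (median 0.43; 1 call, 5 adjusted over the list alone; set test adjusted p = 4.43e-07), among which Clic6 changed with 1.06 (SE 0.162) in the authors' deposited table.

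Markers of microglia, vascular cells and red blood cells did not lie on the positive side as lists. The 17 microglia and macrophage genes had a median of 0.00 (adjusted p = 0.976) and the 17 endothelial and pericyte genes of -0.14 (adjusted p = 0.160). The 3 tested red blood cell genes had a median of -0.28 (adjusted p = 0.143); globin genes are near-identical copies, so their counts are uncertain. Of the 12 genes of meninges and fibroblasts 9 were above 0, with a median of 0.10, and the set test did not pass (adjusted p = 0.375). None of these 4 lists held a member that passed the authors' DESeq2 test, and 1 endothelial gene had an unadjusted p under 0.05. Unipolar brush cell genes, 7 in number, held 1 positive call; their median was -0.07 and the sign of the set test was positive (adjusted p = 0.976). The standard errors of the cell type markers were large: medians of 0.192 for oligodendrocyte, 0.186 for Bergmann glia and 0.189 for endothelial genes, against 0.0987, 0.0987 and 0.126 for genes of like mean expression. Large standard errors go with fold changes pulled more strongly to 0, so sizes cannot be ranked between lists. Xist, the only tested gene of the list of sex-linked genes, had -0.18 (adjusted p = 0.401) in the authors' deposited table, and 0 genes of the Y chromosome are listed there.

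Lists of cell cycle, growth and housekeeping genes held few or no calls and did not pass the set test. None of 55 S phase and DNA replication genes and none of 52 G2 and M phase genes passed the authors' DESeq2 test, and 0 members of these lists had an unadjusted p under 0.05. Their medians were -0.01 and 0.00, with set test adjusted p of 0.834 and 0.976. Their median standard errors of 0.155 and 0.185 were above the 0.0987 and 0.0974 of genes of like mean expression. Medians near 0 therefore do not show that these genes stayed the same. The authors' deposited table gave Plk1, a mitotic kinase, 0.15 (SE 0.177) and the licensing inhibitor Gmnn -0.12 (SE 0.163). The list of negative cell cycle regulators had 1 positive call among 12 members (2 adjusted over the list alone; set test adjusted p = 0.778), the antiproliferative gene Btg2 with 0.34 (SE 0.0906, adjusted p = 0.00918) in the authors' deposited table. The p53 targets had 0 calls among 26 and 1 member at an unadjusted p under 0.05 in the authors' DESeq2 test (set test adjusted p = 0.456). Among 17 Wnt beta-catenin targets Lgr5 alone changed, with -0.65 (SE 0.115, adjusted p = 4.69e-06) in the authors' deposited table, and the set test gave an adjusted p of 0.432. Immediate early and stress genes were positive as a list (3 of 21 called, 4 adjusted over the list alone; median 0.17; set test adjusted p = 0.000824). The transcription factor genes Egr1 and Nr4a1 had 0.49 (SE 0.105) and 0.48 (SE 0.148) in the authors' deposited table, beside Btg2. Spliceosome genes (54 tested, median -0.05), cytosolic ribosomal protein genes (79, median 0.02) and oxidative phosphorylation genes (71, median 0.02) held 0 calls by the authors' DESeq2 test, with 0, 2 and 0 members at an unadjusted p under 0.05 and set test adjusted p of 0.0716, 0.39 and 0.614. Of 24 cholesterol synthesis genes Mvd changed, with -0.33 (SE 0.0899) in the authors' deposited table (set test adjusted p = 0.39).

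**Figure D2:**
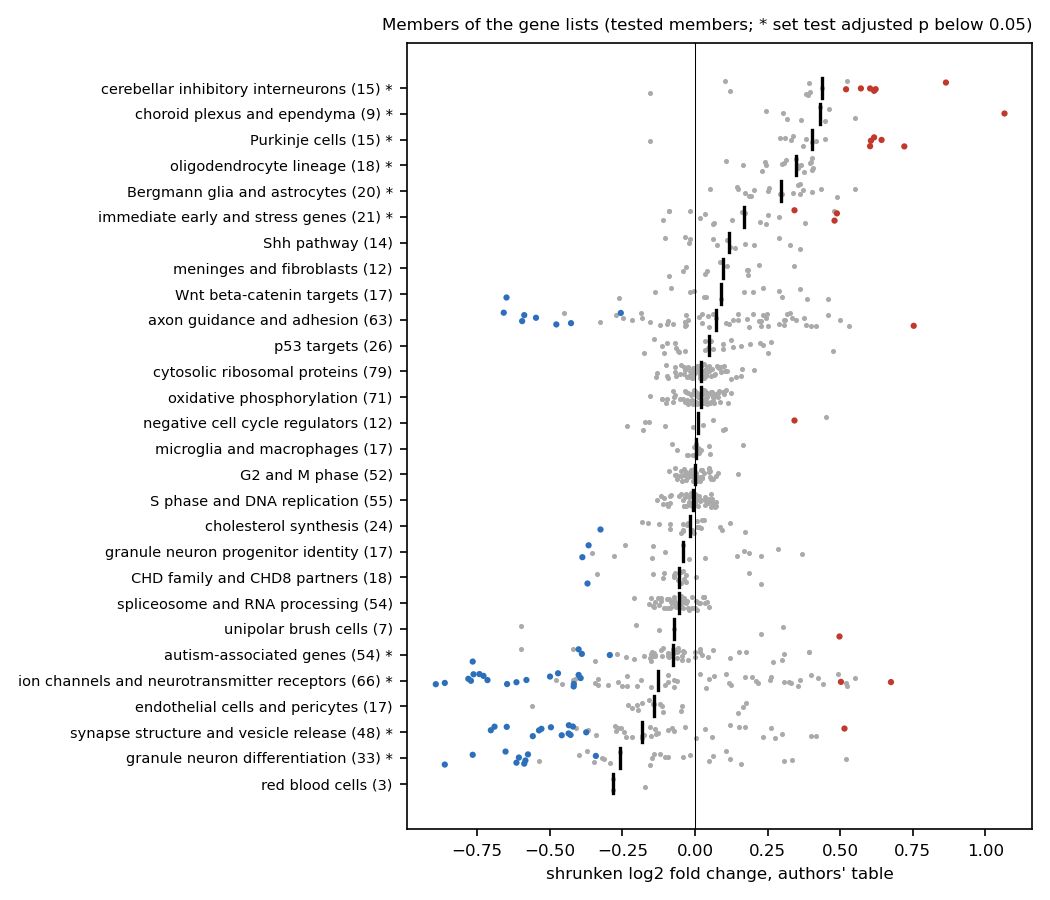
Shrunken log2 fold changes of the authors' deposited table (horizontal axis) for the tested members of each gene list fixed beforehand (rows, number tested in brackets), with members past an adjusted p of 0.05 in colour and a black bar at each list's median. Lists are sorted by median for display only, since shrinkage differs between them. Medians include 0.44 for cerebellar inhibitory interneurons and -0.26 for granule neuron differentiation, and 10 lists pass the set test.

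CHD8 binding was given as 1 peak list that pooled both ChIP libraries of wild-type cells against both pooled inputs, so peaks have no replicate check. Fold enrichment and pileup are the authors' values per peak. The list held 5570 peaks with a median width of 625 bp (quartiles 415 and 993 bp) and a median fold enrichment of 4.33 (quartiles 3.41 and 5.72). It rested on 44347463 fragments kept of 67547572 for CHD8 and on 48436005 kept of 56354066 for input. The strongest peak, on chromosome 19 from 3766483 to 3769674 (mm10) with a fold enrichment of 68.1, spanned an end of Kmt5b, a histone H4 lysine methyltransferase gene. Its summit lay inside the gene, 1077 bp from that end. The next, at 27.4 to 24.2, had their summits nearest to ends of Nudcd3, Srek1, Ufc1, Akt1s1, Cradd, Kdm5d and Ogt, at 1326, 511, 312, 175, 8, 136 and 4 bp. Strand and exons were not used here, so which end starts transcription is not stated.

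Most CHD8 summits lay at gene ends. Of the 5545 summits on the numbered, X and Y chromosomes, 4383 (79.0%, 95% Wilson interval 78.0 to 80.1%) were within 1 kb of an annotated gene end, against 6.58% (6.37 to 6.78%) of 55450 random positions on the same chromosomes. The median distance to a gene end was 206 bp for summits and 16660 bp for random positions. A further 8.37% of summits were inside genes and 2.51% outside genes at over 3 kb from any end, against 39.3% and 44.5% of random positions. These intervals cover counting error only.

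**Figure D3:**
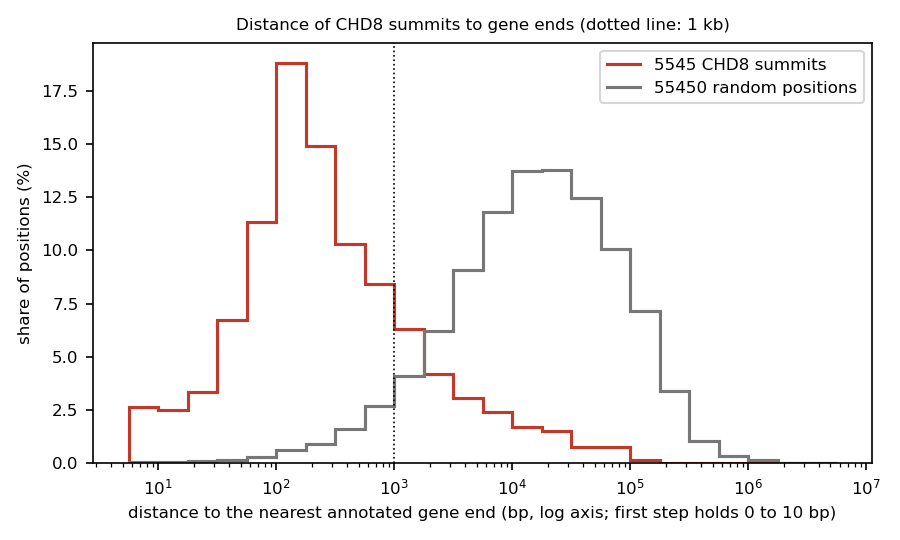
Share of positions (vertical axis, %) by distance to the nearest annotated gene end (horizontal log axis, bp) for 5545 CHD8 summits and 55450 random positions. Summits centre on a median of 206 bp and random positions on 16660 bp, and 79.0% against 6.58% lie left of the dotted line at 1 kb.

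Genes with a CHD8 summit at an end changed less often than genes without one. Of the 15247 tested genes with a position, 4830 (31.7%) had a summit within 1 kb of an end, and 65 of these changed (1.35%), against 440 of 10417 without a summit (4.22%). Genes that a peak overlaps but whose ends lie over 1 kb from any summit, such as Zic2 and Zic4, count as without a summit. Put the other way, 12.9% of changed genes had a summit, against 32.3% of the others (odds ratio 0.309, 95% interval 0.238 to 0.402; Fisher exact p = 2.68e-23). Positive genes had a summit in 8 of 194 cases (4.12%, odds ratio 0.0901, Fisher exact p = 4.08e-22) and negative genes in 57 of 311 (18.3%, odds ratio 0.470, Fisher exact p = 5.18e-08). The difference between negative and positive genes passed its own test (odds ratio 5.22, Fisher exact p = 1.08e-06). Within 10 bins of mean expression the common odds ratio was 0.250 (95% interval 0.190 to 0.329, Cochran-Mantel-Haenszel), with 0.119 (0.0583 to 0.242) for positive and 0.314 (0.233 to 0.424) for negative genes. The odds ratio between the directions fell to 3.19 there (1.42 to 7.18, a test added after the data were seen). All of these tests are across genes, which are not independent replicates.

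Among negative genes with a summit the 6 with the smallest adjusted p were Neurod2, given above, and in the authors' deposited table Celf4, an RNA-binding protein gene (-0.41, SE 0.0726), Zfhx2 (-0.53, SE 0.0999), Ralyl (-0.70, SE 0.132), the calcium pump gene Atp2b1 (-0.36, SE 0.0697) and Trim46 (-0.40, SE 0.0806). Zfhx2 overlaps its antisense gene, and the use of strand in counting is not given in the sources used here, so their counts are uncertain. The 6 of the 8 positive genes with a summit that had the smallest adjusted p were Egr1, Btg2 and, in the authors' deposited table, Myom1 (0.64), Ppp1r1b (0.70), the nuclear receptor gene Rora (0.61) and Dusp10 (0.40).

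**Figure D4:**
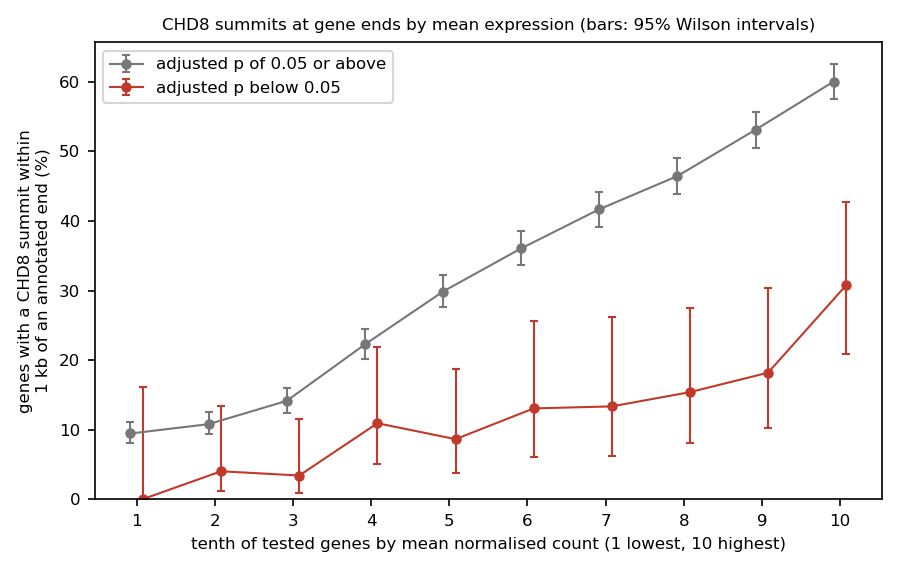
Share of genes with a CHD8 summit within 1 kb of an annotated end (vertical axis, %) in 10 equal bins of mean normalised count (horizontal axis), for genes past and not past an adjusted p of 0.05, with 95% Wilson intervals. In the highest bin the shares are 30.8% and 60.1%, and in each of the 10 bins the changed genes lie below the others.

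CHD8 summits were frequent in some gene lists and rare in others, compared with all other tested genes regardless of their expression. Summits lay at ends of 46 of 54 spliceosome genes (85.2%, where 52.9% was expected from genes of like mean expression; odds ratio 12.5, Fisher exact test with an adjusted p of 6.92e-15), 64 of 79 cytosolic ribosomal protein genes (81.0%, 54.7% expected; odds ratio 9.31, adjusted p = 4.78e-18) and 44 of 71 oxidative phosphorylation genes (62.0%, 44.8% expected; odds ratio 3.54, adjusted p = 2.03e-06). Negative cell cycle regulators had a summit in 8 of 12 cases (66.7%, odds ratio 4.32) and did not pass (adjusted p = 0.0536). Autism-associated genes had a summit in 26 of 54 cases (48.1%, odds ratio 2.01, adjusted p = 0.0349), but 49.2% was expected from genes of like mean expression and the call was lost there (adjusted p = 0.889, an exact test within 10 bins of mean expression chosen after the data were seen). Ion channel and receptor genes (6 of 66, 9.09%, 36.7% expected, odds ratio 0.215, adjusted p = 0.000170) and axon guidance and adhesion genes (8 of 63, 12.7%, 38.1% expected, odds ratio 0.313, adjusted p = 0.00340) had fewer than other genes. Microglia, endothelial, oligodendrocyte and meningeal lists held 0 members with a summit out of 17, 17, 18 and 12, with Fisher exact adjusted p of 0.00898, 0.00898, 0.00690 and 0.0349. For Wnt targets it was 1 of 17 (adjusted p = 0.0462). Cell cycle lists were close to the 31.7% of all genes, with 38.2% for S phase and 38.5% for G2 and M phase (adjusted p = 0.365 for both). From genes of like mean expression 43.0% and 48.2% were expected, and 45.0% for the Shh pathway genes that follow. The exact test within bins made no call for these lists. For granule neuron differentiation genes the share was 18.2% (6 of 33, adjusted p = 0.188) and for Shh pathway genes 28.6% (4 of 14, adjusted p of 1). The exact test within bins of mean expression kept the other 10 calls and gave further calls, all with fewer summits than expected: granule neuron differentiation (49.4% expected, adjusted p = 0.000500), synapse structure and vesicle release (9 of 48, 47.0% expected, adjusted p = 0.000173), cholesterol synthesis (4 of 24, adjusted p = 0.00684), Bergmann glia and astrocytes (3 of 20, adjusted p = 0.00114) and inhibitory interneurons (1 of 15, adjusted p = 0.00967).

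Long genes were called as changed more often than short ones, in both directions, in counts not adjusted for mean expression. Whether a change is simply easier to call in long genes was not tested. Among the longest 10% of genes (above 135.7 kb) 8.79% changed, 45 positively and 89 negatively, against 1.70% of the shortest 10%, and 26.5% of changed genes were in the longest 10% against 9.44% of the others (odds ratio 3.47, 95% interval 2.82 to 4.26; Fisher exact p = 3.41e-27, a test added after the data were seen). Length and signed log2 fold change had a Spearman rho of only 0.0336 across 15247 genes (permutation p = 8.00e-05, two-sided, across genes), and the median log2 fold change was 0.00 in the shortest and 0.04 in the longest 10%. Among genes with a mean count of at least 100 this rho was 0.0163 and did not pass (permutation p = 0.0732), whereas the partial rho given mean expression was 0.0857 over all 15247 genes (permutation p = 1e-05, the smallest the permutations can give).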

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

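The tests in this part were chosen after the results they bear on had been seen, except that the odds ratios of the third pattern had been planned. A first signal outside the comparisons is that 18 CHD8 peaks lie on the unplaced contig JH584304, with fold enrichments between 1.48 and 2.51. They are among 43 peaks with a pileup over 1000, against a median of 42 over all peaks. The highest of these, on chromosome 2 from 98666664 to 98667188, has a pileup of 33297 and a fold enrichment of 1.81. Many others of the 43 lie close together on chromosome 9, between 3000123 and 3038242. Fold enrichments of the 43 run from 1.48 to 2.56, below the median of 4.33 over all peaks. The 43 count among the 5570 peaks, and whether they mark CHD8 binding was not tested.

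A second signal outside the comparisons is that 7 genes without an adjusted p have a p-value under 0.001, and 5 of the 7 names are muscle genes: Ckm, Mymk, Myoz2, Mypn and Csrp3, named after their values were seen. In the authors' deposited table Ckm, muscle creatine kinase, has a log2 fold change of 1.09 (SE 0.184) at a mean normalised count of 7.59 and Mymk, which codes for a protein of myoblast fusion, of 0.97 (SE 0.187) at 8.85.

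The first pattern is the set of positive skeletal muscle genes. In lists written after the changed genes had been seen, 20 of 25 tested sarcomere genes were positive calls (median 0.94), with Myl1, Acta1 and Actn2 at 2.04, 1.71 and 1.54 in the authors' deposited table, and 4 of 5 myogenic genes, with Myog at 1.64 and Myod1 at 0.64 in the authors' deposited table; 0 genes of these lists are in a list fixed beforehand. Binding of CHD8 at the ends of most of these genes is argued against, since 24 of the 25 positive muscle genes had no summit there and 1 had (4%, upper 95% Wilson bound 19.5%), although this is no fewer by test than the 3.14 expected from genes of like mean expression (permutation p = 0.310). Skeletal muscle carried over into some libraries cannot be told apart from expression of muscle genes in the progenitors themselves: 12 of the 12 muscle membrane and metabolism genes without an adjusted p were positive, which both predict, and these genes have low means and were listed after the pattern was seen. The 9 tested members of that list held 1 call, with 8 above 0, 1 below and a median of 0.31. Of the 25 tested sarcomere genes 2 were below 0, Mybpc2 at -0.41 and Actn3 at -0.06 in the authors' deposited table, and neither passed. Genotype, Cre driver and a single deviating library stay open, as untested.

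The second pattern is the positive markers of inhibitory neurons and neural glia beside negative granule neuron genes. Whether a lower share of granule lineage cells raised every other type alike is not settled by these markers. Of 34 microglia, endothelial and pericyte genes 38.2% had positive fold changes, against 98.4% of 63 neural markers (Fisher exact p = 1.71e-11). Their medians of -0.03 and 0.36 lie apart by more than 2 median standard errors of 0.186. However, the neural markers came from lists already seen to be positive, without unipolar brush cell genes (3 of 7 above 0). Markers of 1 cell type can also move together, which the Fisher test ignores. Of the meningeal genes 9 of 12 and of the choroid plexus and ependyma genes 9 of 9 were positive. With both lists added (56.4% of 55) the medians lie apart by 0.35, just under 2 median standard errors of 0.187. As lists, microglia and endothelial genes did not share the positive shift of the neural markers. Dilution as the source of the negative granule genes cannot be told apart from other causes: 54.2% of 107 cell cycle genes were negative against 75.8% of 33 differentiation genes (Fisher exact p = 0.0417), but the standard errors of cell cycle genes (median 0.173) are too large beside the difference of 0.25 in medians. A share of other cells that varied between libraries of a group cannot be told from the standard errors: those of 97 markers exceed those of genes of like mean expression by a median of 0.0671 (permutation p = 1e-05, the smallest the permutations can give), but 121 cell cycle and Shh pathway genes exceed them by 0.0693 (permutation p = 0.821 for the difference). Genotype, Cre driver, and a change within inhibitory neurons or glia stay open, as untested.

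The third pattern is that genes with a CHD8 summit at an end changed less often. Mean expression as the whole cause is argued against, since the common odds ratio within bins of it was 0.250, with an upper 95% bound of 0.329. Precision runs the other way, because genes with a summit had the smaller median standard error (0.104 against 0.152). Positive genes of other cell types as the whole cause are argued against by the odds ratio of 0.470 among negative genes alone. Granule neuron differentiation, synapse and ion channel lists, which held negative calls, also had fewer summits than expected. The odds ratio among negative genes therefore does not set aside a shift in cell composition that acts on both directions. No biological explanation of the pattern was tested, and it stays open.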

How the results depend on the processing

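Settings without the muscle and other cell type genes, with protein-coding genes alone, and with list binding within bins of mean expression were chosen after seeing the data. The 513 changed genes became 276 at an adjusted p below 0.01, 288 with an absolute log2 fold change of at least 0.5 and 24 with at least 1, each by the stricter threshold itself; other settings gave 452 to 715. The share of negative genes, 61.8%, became 25% with an absolute value of at least 1, 52.8% with at least 0.5 (exact binomial p = 0.377), 57.9% at an adjusted p below 0.1 and 67.8% below 0.01, and lay between 60.9 and 67.3% in the other settings; the cause was not tested. Peaks numbered 3192 with q below 1e-10, where the meaning of q is uncertain because the file headers say it was not calculated, and 1967 with a fold enrichment of at least 5, by construction. Summits within reach of a gene end, 79.0%, became 83.4% with fold enrichment of at least 5, 81.6% with q below 1e-10, 83.2% for any part of the peak and 89.1% within 3 kb; the cause was not tested. Lists with a binding call numbered 11, 15 within bins of mean expression, where autism-associated genes lost theirs, 12 within 3 kb and 6 with the stronger 50% of peaks, where fewer genes have a summit. The rho of gene length lost its call at a mean of at least 100 (0.0163; the cause was not tested) and was 0.0857 given mean expression.

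The odds ratio of binding and change stayed below 1 and past the threshold in all 9 alternatives run, between 0.250 and 0.413, and the adjusted p of Chd8 stayed between 0.890 and 0.922. Set tests called 10 lists, and 10 to 15 under the alternatives; over lists and settings, 104 of the 111 single comparisons gave the same call and 7 gained one. On ranks these were Shh pathway (adjusted p = 0.0313), CHD family (0.0364), spliceosome (0.00373), endothelial (0.0467) and red blood cell genes (0.0476), on log2 fold changes endothelial genes (0.0249) and at a mean of at least 100 Shh pathway genes (0.0331); the cause was not tested. No paired analysis was possible because the expression table holds no values per sample. For the same reason leaving out replicates, other normalisations, other filters on counts, the Olig1-Cre controls alone and other splits of the samples were not run, so whether 1 library decides a call is not known. Summed exon length was not run because exons were not used here.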

Other observations

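The widest CHD8 peak, 19446 bp on chromosome 14 from 122471425 to 122490870, overlapped Zic2, and others among the 8 widest overlapped Nfib (13838 bp), Zic1 and Zic4 (11861 bp), Pax6 (10338 bp), Uncx (8874 bp) and Meis1 (7715 bp), genes chosen after their peaks had been seen. The second widest (16447 bp, chromosome 13) overlapped C130071C03Rik and Gm52046, and the fifth (11220 bp, chromosome 15) overlapped no annotated gene. Fold enrichments were 8.67 at Zic2, 11.5 at Zic1 and Zic4, 8.26 at Uncx and 7.92 at Pax6, against a median of 4.33 and an upper quartile of 5.72 over all peaks. At Nfib and Meis1 they were 5.28 and 5.61, below that upper quartile. The hypothesis that genes at the 50 widest peaks (at least 3734 bp) have more negative fold changes than genes at other peaks was written before its test was run. However, Zic1, Zic2, Zic4 and Pax6 belong to the list of granule neuron progenitor identity and had negative values, given above. Whether the hypothesis was blind to those values is not known. Median log2 fold changes were -0.14 at the widest peaks and -0.03 at other peaks. The median Wald statistic of the authors' deposited table was -1.08 for 44 genes at the widest peaks and -0.30 for 5032 genes at other peaks, a difference of -0.773 (permutation p = 2.00e-05, across genes). Of the 44 genes 37 had negative fold changes (84.1%, against 62.6%), but only Zic1 and Zic4 passed an adjusted p of 0.05, and the share of changed genes did not differ by the test used (4.55% against 1.47%, Fisher exact p = 0.140).

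Imprinted genes were looked at because H19, Grb10 and Zdbf2 are all positive, so this test was chosen after that result had been seen. The 41 tested imprinted genes held 3 positive and 2 negative calls, and the 3 positive ones are those that prompted the test. Without them 2 of 38 changed (5.26%, against 3.31% of other genes; Fisher exact p = 0.360), which leaves open whether imprinted genes change more often. Zdbf2 stood at 0.64, and Kcnk9 and Usp29 at -0.74 and -0.43, in the authors' deposited table, so the changed members went both ways, and a set test on the direction of all 41 gave p = 0.0563. Igf2, the neighbour of H19, stood at 0.18 (SE 0.194, adjusted p = 0.795) in the authors' deposited table.

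Within 5 Mb of Chd8 on chromosome 14, 9 of 117 tested genes changed (7.69%, against 3.28% elsewhere; Fisher exact p = 0.0157, a window chosen after the data were seen). Of these 8 were negative, among them Jph4 at -0.61 (SE 0.0904), Zfhx2 at -0.53 and Psmb5 at -0.42 in the authors' deposited table, and Slc35f4 was positive at 0.74. The 8 also include Zfhx2os, the antisense gene that Zfhx2 overlaps, at -0.59 in the authors' deposited table. The 9 genes are therefore not all separate loci, and the cause of their changes was not tested.

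In the muscle membrane and metabolism list 1 of 9 tested genes was called, Mb with 0.69 (SE 0.189) in the authors' deposited table, and Eno3 stood at 0.12 (adjusted p = 0.759) there. Set tests gave adjusted p of 1.10e-79 for sarcomere genes, 5.32e-11 for myogenic genes and 0.00608 for membrane and metabolism genes, on lists written after the pattern had been seen.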
